A study of Homo sapiens with 24 samples.

How the data were processed

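Total RNA was sequenced from 4 human small-cell lung cancer cell lines (H187, H209, H82 and SHP-77), each treated for 24 h with 0.1 nM lurbinectedin or with DMSO. The series design text states biological triplicates, which gives 24 samples in 8 groups of 3. It names H187 and H209 as ISL1 high and H82 and SHP-77 as ISL1 low. Per the labels' protocols, cells were grown in RPMI-1640 with serum, RNA was purified on RNeasy Plus columns, and 100 ng went into Illumina Stranded Total RNA libraries with Ribo-Zero Plus depletion of ribosomal RNA.

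Per the submitters' processing notes, the authors used STAR 2.7.10a, featureCounts (version not given), Subread 2.0.3 and edgeR 4.2.0 on the hg38 genome. The gene annotation and the filter on low counts are not stated there. The authors deposited 5 tables: 1 per line, comparing lurbinectedin with DMSO, and 1 comparing the ISL1-high with the ISL1-low lines under lurbinectedin in 12 samples. Per the file headers, each table holds raw counts per gene and sample as the authors deposited them. It also holds the authors' log2 counts-per-million (CPM) values for each sample, which are normalized within that table. The authors' log2 fold change, their signed fold change, and their p-value and FDR stand beside these in the deposited tables, with each gene's position and length.

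The tables list 14023 genes for H187, 14421 for H209, 13516 for H82, 14190 for SHP-77 and 14463 for the class comparison. The smallest row maximum over these tables is 15 counts and the smallest row sum is 59, so genes with low counts had been left out before deposition. The 4 line tables share 11408 genes, and 16795 genes are in at least 1 table. The counts of the treated samples were checked between the line tables and the class table and were identical in every cell. Symbols are those of the files, several of them older HGNC symbols. The mitochondrially encoded transcripts are not listed, so that list (0 of 13 genes) was not analysed here. NEUROD1, MYC, MYCN and SLFN11 are not among the 11408 shared genes and enter only the comparisons whose tables list them.

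Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr at its defaults (minimum count 10, minimum total 15), TMM scaling, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values are edgeR's unless another tool is named. Each line was fitted alone on its 6 samples. The difference in response was tested on all 24 samples with a mean per line and treatment, as the mean effect in H187 and H209 minus that in H82 and SHP-77. The class differences under DMSO and under lurbinectedin were tested on 12 samples each with a mean per line. In these 3 comparisons the lines are fixed, so the results hold for these 4 lines. Fold changes are log2 with the standard error (SE) of the fit. Levels are in CPM on TMM-scaled library sizes, given as mean ± SD. They can differ slightly between the fit of a line and that of a class, since each has its own scaling. A gene was counted as shared by the 4 lines if it passed in all 4 fits in the same direction, against the number that independent lists of those sizes would share.

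34 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) within each comparison, where at least 5 members were measured, adjusted over the lists of that comparison. camera with an estimated correlation and fry were run beside it. fry tests whether a list's genes move one way on balance and does not compare them with other genes. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone.

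The genes named follow a rule: a panel (ISL1, NEUROD1, INSM1, MYC, MYCL, MYCN, DLL3 and SLFN11), the 6 largest rises and 6 largest falls per comparison among protein-coding genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, and the 3 members with the smallest p of each passing list, limited to 5 lists where more than 30 genes result. Some genes that meet this rule and 1 gene list are not reported here, though they count in the totals. For the class comparisons the same sign in all 4 pairs of a high and a low line took the place of non-overlap. Groups, comparisons, gene lists, this rule and the first set of alternatives were fixed before the data were examined. Genes named outside the rule are given as chosen after their values were seen.

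The alternatives fixed at that stage were RLE size factors, no filter on low counts or a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, replicate number as a block, all 24 samples in 1 fit, an absolute log2 fold change of at least 1, class as the only term, limma on 1 value per line, the same sign in all 4 line pairs, the authors' deposited table, and leaving out each library in turn. Added after the data were seen were a correction for transcript GC content within each library (lowess, span 0.3), leaving out the abundant non-coding RNAs, single pairs of lines, the class comparison on shared genes only, leaving out each library, the other filters and DESeq2 for the genes shared by the 4 lines, and RLE size factors for the gene lists. Genomic span was taken from the first to the last exon in the tables and GC content from reference transcripts (Biostrings 2.70.1). Figures were drawn in Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

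The procedure was tested on simulated data with 200 changed genes per comparison. True changes of 1.25-fold were recovered for 74.6% of genes in H187, 68.7% in H209, 70.1% in H82, 67.2% in SHP-77, 77.6% in the difference in response, 82.1% in the class comparison under DMSO and 71.6% in that under lurbinectedin. For 2-fold changes the shares were 90.9%, 95.5%, 93.9%, 93.9%, 100%, 100% and 97.0%. Over each whole comparison 12 of 197, 13 of 199, 16 of 207, 9 of 190, 5 of 207, 10 of 224 and 24 of 212 calls were false. In H187, H209, H82 and the class comparison under lurbinectedin that share lies above the 5% aimed at. Of simulated lists of 30 genes moved by 1.25-fold, 7 of 7 were called at an unadjusted camera p under 0.05, and 0 of the unmoved ones. The measured lists were judged at an adjusted p, so recovery of lists at that threshold was not tested. The simulated genes varied independently of each other. False calls of lists whose genes vary together were therefore not tested.

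Total counts per sample were 24226553 to 36415190. Where every library of a group had 0 counts, a fold is given as a lower bound against a floor of 3 counts per library. Such floors cover counting error only.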

Results

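The data were gene-level counts of total RNA from 4 small-cell lung cancer lines, a neuroendocrine lung tumour type. Lurbinectedin is an alkylating drug that binds guanines in the minor groove of DNA and stalls elongating RNA polymerase II. ISL1 is a LIM homeodomain transcription factor of motor neurons and endocrine cells. The design sets ISL1-high lines (H187 and H209) against ISL1-low lines (H82 and SHP-77), so it asks whether the response to the drug differs between them. Each line had 3 DMSO and 3 lurbinectedin libraries. Total counts per library were 25678767 to 31675679 in H187, 24226553 to 30711318 in H209, 30425305 to 36415190 in H82 and 26616718 to 33735391 in SHP-77. The transcripts RN7SK, RN7SL1, RN7SL2 and RPPH1 together took 3.10% to 5.40% of a library's counts.

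ISL1 (hg38 chromosome 5, 51383124 to 51394729) separated the lines as the design names them. Under DMSO it stood at 252 ± 10.0 CPM in H187 and 215 ± 7.00 in H209, against 3.62 ± 0.305 in H82 and 0.912 ± 0.0291 in SHP-77 (mean ± SD, n = 3 each). Lurbinectedin lowered it to 221 ± 4.23 CPM in H187 and 173 ± 4.44 in H209. The log2 fold change was -0.19 ± 0.04 (SE, adjusted p = 0.0010) in H187 and -0.31 ± 0.03 (adjusted p = 9.2e-11) in H209. In H82 (0.05 ± 0.15) and SHP-77 (-0.41 ± 0.27) no change of ISL1 was detected, and the difference in response was not detected either (-0.07 ± 0.13, adjusted p = 0.72). NEUROD1 was highest in H82 at 268 ± 9.02 CPM, and MYC was highest in H82 at 1994 ± 41.8 CPM.

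**Figure D1:**
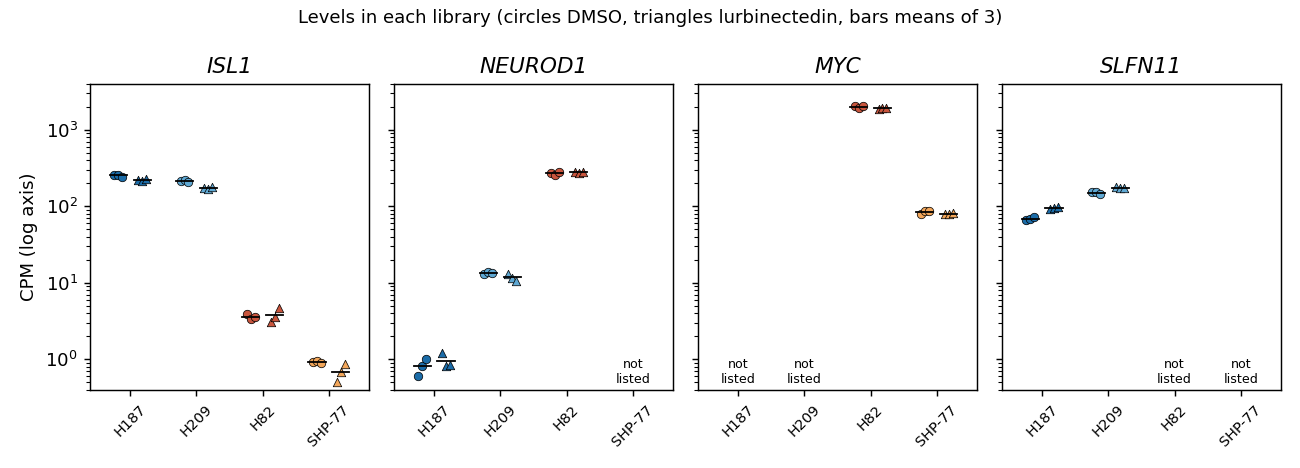
Levels in CPM (log axis) of ISL1, NEUROD1, MYC and SLFN11 in each library, by line and treatment, 3 libraries per group. Lines for which a gene is not listed are marked so. ISL1 lies at 173 to 252 CPM on average in H187 and H209 and at 0.680 to 3.76 CPM in H82 and SHP-77.

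In H187, lurbinectedin raised stress-response genes and lowered long genes. PHGDH, a serine synthesis enzyme (hg38 chromosome 1, 119711796 to 119744226), went from 15.0 ± 0.831 to 47.4 ± 1.22 CPM, a log2 fold change of 1.66 ± 0.06 (SE, n = 3 per group, adjusted p = 3.7e-14). CHAC1, INHBE and ATF3 rose by 1.64, 1.61 and 1.42 on the log2 scale. LSAMP, an axonal adhesion gene that spans 643 kb (chromosome 3, 115802363 to 116445538), dropped from 12.9 ± 0.389 to 1.15 ± 0.359 CPM, a log2 fold change of -3.46 ± 0.15. MACROD2, which spans 2058 kb, changed by -2.61, and PARD3B, PTPRG, SLIT3 and LINGO2 by -1.97 to -1.73. In the panel, SLFN11, a helicase-like gene whose product blocks stalled replication forks, rose from 68.6 to 94.6 CPM (0.46 ± 0.04), while INSM1 (-0.21), DLL3 (-0.22) and MYCN (-0.39) fell. Of 14023 genes tested, 1708 were higher and 1778 lower, 24.9% of the total, and 114 changed at least 2-fold (24 higher, 90 lower).

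Genes for DNA replication moved up in H187 and genes for mitosis moved down. Of 42 DNA replication and E2F genes, 39 rose and 1 fell (40 and 1 adjusted over the list alone, median 0.30, list adjusted p = 4.4e-21), with RRM2 at 0.50, CDT1 at 0.62 and CDC6 at 0.60. Of 40 G2/M and mitosis genes, 31 fell and 0 rose (32 and 0 adjusted over the list alone, median -0.27, adjusted p = 3.5e-15, and adjusted p = 0.25 with an estimated correlation), among them PLK1 (-0.81), CENPA (-0.72) and KIF20A (-0.62). Of 27 synaptic and axonal long genes, 25 fell (25 adjusted over the list alone, median -0.81, adjusted p = 2.8e-19). Of 26 integrated stress response genes, 20 rose (20 adjusted over the list alone, median 0.40, adjusted p = 4.0e-12). Homologous recombination (15 of 29 up, 1 down, median 0.17, adjusted p = 3.1e-07), interferon-stimulated genes (11 of 24 up, 0.29, 5.3e-07) and NF-kB targets (9 of 19 up, 0.24, 4.4e-05) also passed upward. With an estimated correlation 6 of these lists kept their call: replication, long genes, stress response, recombination and interferon at adjusted p = 0.027 and NF-kB at 0.047.

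Other lists that passed in H187 lost their call with an estimated correlation, at the adjusted p given second here. Cytosolic ribosomal proteins (25 of 73 down, median -0.10, 6.2e-07 and 0.50), nuclear-encoded oxidative phosphorylation (16 of 49 down and 1 up, 3.0e-05 and 0.43) and lineage transcription factors (8 of 14 down, 0.0046 and 0.25) were lower. So were the unfolded protein response (7 of 22, 0.019 and 0.43), heat shock genes (5 of 20, 0.021 and 0.25) and neuroendocrine markers (10 of 26 down and 3 up, 0.026 and 0.25). Immediate early and short-lived transcripts (10 of 28 up and 3 down, 0.0048 and 0.11), the Fanconi anaemia pathway (7 of 21 up, 0.021 and 0.25) and the DNA damage checkpoint (9 of 21 up and 3 down, 0.044 and 0.25) were higher.

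H209 had the largest number of changed genes of the 4 lines. ATF3, a stress-induced transcription factor (hg38 chromosome 1, 212565334 to 212620777), rose from 25.5 ± 0.696 to 147 ± 4.19 CPM, a log2 fold change of 2.53 ± 0.04 (SE, n = 3 per group, adjusted p = 2.5e-40). TRIB3 rose from 52.6 to 216 CPM (2.04 ± 0.03), BBC3, a pro-apoptotic BH3-only gene, from 2.49 to 12.7 CPM (2.35 ± 0.12), and HOXB9 from 5.48 to 23.7 CPM (2.10 ± 0.08). SGCD (-2.91), ERBB4 (-2.53), LINGO2 (-2.15), PARD3B (-2.11), PTPRG (-1.97) and NPAS3 (-1.94) fell most within the naming rule, and each of them spans at least 441 kb. In the panel SLFN11 (0.21) and INSM1 (0.17) rose and MYCL (-0.22) fell. NEUROD1 went from 13.4 to 11.7 CPM, a call lost without 4 of the 6 libraries (adjusted p up to 0.28). DLL3 went from 132 to 120 CPM (-0.14 ± 0.04), a call lost without DMSO 3 (adjusted p = 0.10). Of 14421 genes tested, 3273 were higher and 3240 lower, 45.2% of the total, and 231 changed at least 2-fold (121 higher, 110 lower).

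The lists that moved in H187 moved the same way in H209, except those named here. Of 27 integrated stress response genes 27 rose (27 adjusted over the list alone, median 0.88, adjusted p = 1.9e-19), including CEBPB (1.96) and DDIT4 (1.35). Of 42 replication genes 40 rose and 1 fell (40 and 1 adjusted over the list alone, median 0.33, adjusted p = 7.3e-16, and adjusted p = 0.058 with an estimated correlation), with E2F2 at 0.89 and CDT1 at 0.82. Of 40 mitosis genes 37 fell (37 adjusted over the list alone, median -0.41, adjusted p = 2.6e-16, and adjusted p = 0.058 with an estimated correlation), with CCNB1 at -0.92. Of 28 synaptic and axonal long genes 25 fell (25 adjusted over the list alone, median -0.97, adjusted p = 4.5e-14), with NRXN3 at -1.22. The stress response (0.018) and the long genes (0.021) were the 2 lists that passed with an estimated correlation. Replication-dependent histones passed upward in H209 (29 of 41 up, 7 down, median 0.15, adjusted p = 0.0011, and adjusted p = 0.62 with an estimated correlation), and cholesterol biosynthesis passed downward (12 of 25, 0.0062, and 0.33 with an estimated correlation). The unfolded protein response (4 up and 14 down of 22, median -0.14, mean 0.01), neuroendocrine markers (6 up and 12 down of 26) and the DNA damage checkpoint (10 up and 5 down of 21) did not pass camera (adjusted p = 0.11, 0.12 and 0.12). fry called the second (0.015) and the third (0.0011).

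Other lists in H209 lost their call with an estimated correlation, at the adjusted p given second. Upward went immediate early and short-lived transcripts (22 of 30 up and 2 down, 6.6e-08 and 0.058), homologous recombination (18 of 29 up and 3 down, 1.6e-05 and 0.12) and NF-kB targets (12 of 16, 1.7e-04 and 0.058). Interferon-stimulated genes (9 of 26 up and 1 down, 0.0050 and 0.099) and the Fanconi anaemia pathway (12 of 21 up and 1 down, 0.0055 and 0.10) were also higher. Downward went cytosolic ribosomal proteins (49 of 73, median -0.11, 6.0e-08 and 0.44), heat shock genes (17 of 21 down and 1 up, 8.9e-07 and 0.058), oxidative phosphorylation (32 of 49, 8.9e-07 and 0.33) and lineage transcription factors (8 of 13 down and 2 up, 0.017 and 0.23).

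H82 had the smallest number of changed genes in the main fits, and that number depended on single libraries. Its rank below SHP-77 turned with all 24 samples in 1 fit (643 against 451), with a replicate block (755 against 561) and without H82 DMSO 3 (1397 against 737). DCC, an axon guidance receptor gene that spans 1196 kb (hg38 chromosome 18, 52340172 to 53535903), fell from 41.0 ± 2.30 to 28.6 ± 1.78 CPM, a log2 fold change of -0.52 ± 0.06 (SE, n = 3 per group, adjusted p = 7.1e-05). NEGR1 (-0.83), CTNNA2 (-0.78), THSD7B (-0.74) and CNTN5 (-1.29) fell, and the histone gene HIST1H1D fell from 124 to 95.3 CPM (-0.38 ± 0.04). MACROD2 (-0.76) fell too, a call lost without 3 of the 6 libraries (adjusted p up to 0.086). Within the naming rule the largest rises were small and at low levels: OLFML3 from 1.51 to 2.63 CPM (0.79 ± 0.17), and CCDC136, ABTB1, AMN, C1QTNF4 and CCS by 0.54 to 0.74. Each of these 6 lost its call without at least 1 library, OLFML3 without lurbinectedin 1 (adjusted p = 0.070) or lurbinectedin 3 (0.056) and C1QTNF4 without lurbinectedin 2 (0.051). CCDC136 lost it without 4 of the 6 libraries and ABTB1, AMN and CCS without 5 of the 6, with adjusted p up to 0.15, 0.16, 0.19 and 0.19. In the panel DLL3 rose (0.25 ± 0.05, adjusted p = 0.012), a call lost without 4 of the 6 libraries and after the GC correction (0.14, adjusted p = 0.15). Of 13516 genes tested, 395 changed, 2.92% of the total, 186 of them lower and the rest higher, and 8 changed at least 2-fold (4 higher, 4 lower). The count was 126 without DMSO 1, 195 without DMSO 2, 1397 without DMSO 3, 93 without lurbinectedin 1, 109 without lurbinectedin 2 and 93 without lurbinectedin 3. It was 180 (40 higher, 140 lower) after a correction for transcript GC content, 643 with all 24 samples in 1 fit and 652 in the authors' deposited table.

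In H82, 9 of 30 lists tested passed and none did with an estimated correlation in camera, whose smallest adjusted p was 0.27, while fry called 2. Of 24 synaptic and axonal long genes 9 fell (16 adjusted over the list alone, median -0.28, adjusted p = 5.0e-15, and adjusted p = 0.27 with an estimated correlation). Of 36 replication-dependent histones 13 fell (22 adjusted over the list alone, median -0.14, adjusted p = 3.2e-12, and 0.46 with an estimated correlation). Homologous recombination (0 of 29 genes past the threshold, median -0.06, 0.0022), ribosome biogenesis (1 of 37 down, 0.010) and the integrated stress response (1 of 25 down, 0.029) passed downward, each at 0.46 with an estimated correlation. Cytosolic ribosomal proteins (2 of 73 up, median 0.05, 0.0046) and oxidative phosphorylation (3 of 49 up, 0.029) passed upward, each at 0.62 with an estimated correlation. The Notch pathway (4 of 16 up, 1 down, 0.015) and mesenchymal and non-neuroendocrine genes (1 of 17 up, 0.043) also passed upward, each at 0.46 with an estimated correlation. The replication and mitosis lists did not pass (adjusted p = 0.094 and 0.94). After the GC correction homologous recombination (median -0.03) and oxidative phosphorylation (median 0.04) lost their call, each at adjusted p = 0.064. The replication list then passed downward (median -0.03, 0.020), and the Notch median went from 0.16 to 0.09.

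In SHP-77 the largest changes within the naming rule were again falls of long genes. TENM3, a synaptic adhesion gene that spans 560 kb (hg38 chromosome 4, 182243431 to 182803024), fell from 15.1 ± 1.36 to 6.50 ± 0.267 CPM, a log2 fold change of -1.21 ± 0.08 (SE, n = 3 per group, adjusted p = 4.3e-09). LSAMP fell from 20.0 to 9.85 CPM (-1.02 ± 0.07), and CDH12 (-1.02), MACROD2 (-0.95), CNTN5 (-0.93) and ERBB4 (-0.92) fell. TGIF2 (0.63), FAXDC2 (0.47) and AJUBA (0.46) rose. No panel gene reported here passed the threshold. Of 14190 genes tested, 281 were higher and 456 lower, 5.19% of the total, and 13 changed at least 2-fold (5 higher, 8 lower). The count was 431 without DMSO 2, 417 without lurbinectedin 1 and 436 without lurbinectedin 3, and 451 with all 24 samples in 1 fit.

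Of 26 synaptic and axonal long genes in SHP-77, 17 fell (19 adjusted over the list alone, median -0.24, adjusted p = 7.6e-17, and adjusted p = 0.20 with an estimated correlation). Of 43 replication-dependent histones 18 fell (25 down and 1 up adjusted over the list alone, median -0.11, adjusted p = 1.6e-07, and 0.61 with an estimated correlation), among them HIST1H3J (-0.30). The replication list passed upward (7 of 42 up, 15 up and 3 down adjusted over the list alone, median 0.05, 0.0026, and 0.51 with an estimated correlation), with RRM2 at 0.19 and TK1 at 0.21. Cholesterol biosynthesis (4 of 24 up, 9.0e-04), interferon-stimulated genes (2 of 25 up, 0.048) and the DNA damage checkpoint (2 of 20 up, 0.048) passed upward, each at 0.51 with an estimated correlation. Neuroendocrine markers passed downward (6 of 26, 0.0051, and 0.50 with an estimated correlation). The integrated stress response (0 of 27 genes past the threshold, adjusted p = 0.36) and the mitosis list (3 up and 2 down of 40, 0.45) did not pass.

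**Figure D2:**
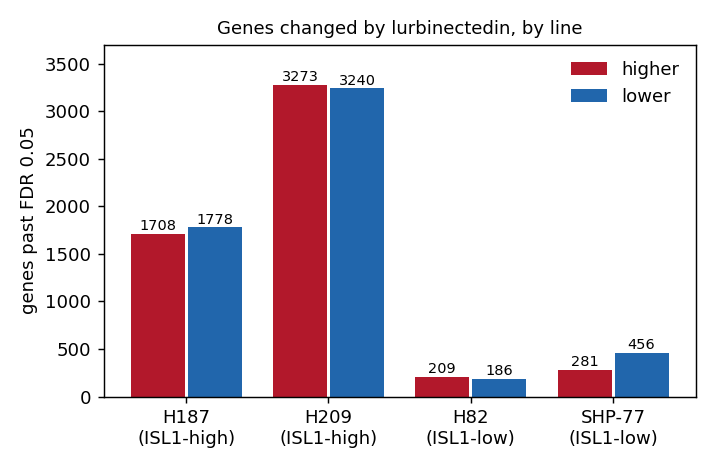
Number of genes higher and lower under lurbinectedin at an edgeR adjusted p under 0.05 in each line, 3 libraries against 3. H209 had 3273 higher and 3240 lower, and H82 had 395 in all, 186 of them lower.

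Among the 11408 genes listed for every line, 63 were lower in all 4 lines and 6 higher, where independent lists of these sizes would share 0.13 and 0.11. The genes lower in all 4 included LSAMP, MACROD2, CDH12, GPC6 and NEGR1, and their median genomic span was 558 kb against 28.2 kb for all 11408. For MACROD2 the call in H82 was lost without 3 of the 6 H82 libraries (adjusted p = 0.061 to 0.086). The 6 higher genes (PITPNM1, PLCB3, PDLIM7, MYORG, SEMA6C and S1PR2, named here because they are few) rose by 0.14 to 0.44 on the log2 scale, and 0 of them passed in all 4 lines after the GC correction. The total of 69 became 54 (0 higher, 54 lower) with that correction. It was 38 without H82 DMSO 1, 32 without H82 lurbinectedin 1, 30 without H82 lurbinectedin 2 and 36 without H82 lurbinectedin 3. It was 104 with all 24 samples in 1 fit. Between H187 and H209, 1044 genes were higher in both and 1103 lower in both, where 363 and 345 would be shared by independent lists, and 62 changed in opposite directions. Between H82 and SHP-77, 21 were higher in both and 79 lower in both, where 3.54 and 4.28 would be shared, and 1 changed in opposite directions. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.64 for H187 and H209 and 0.23 to 0.32 for the other 5 pairs of lines.

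Genes with a longer genomic span had lower fold changes in each of the 4 lines. For genes of 300 to 1000 kb the median log2 fold change was -0.39 in H187, -0.44 in H209, -0.16 in H82 and -0.18 in SHP-77, and 76.2%, 79.2%, 20.3% and 41.6% of them were called lower. For genes under 10 kb the medians were 0.02, 0.04, 0.05 and 0.02. Spearman's rho of log2 fold change with span was -0.261, -0.256, -0.330 and -0.282 across genes, which are not independent replicates. In each line the median over genes of 300 kb or more was lower in the treated library in all 9 treated-control pairs. Those pair medians ran from -0.442 to -0.314 in H187, -0.428 to -0.381 in H209, -0.185 to -0.125 in H82 and -0.203 to -0.164 in SHP-77, while replicate pairs of a group stayed within 0.0781 of 0. After the GC correction the medians of these genes were -0.39, -0.43, -0.14 and -0.18.

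**Figure D3:**
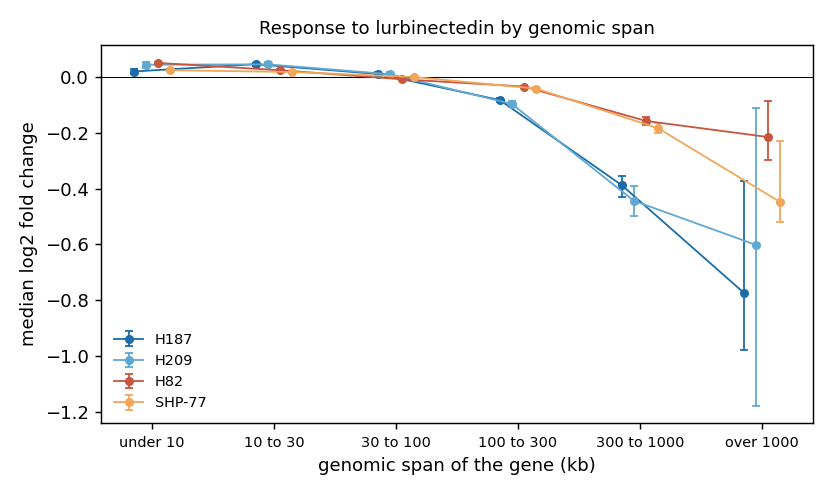
Median log2 fold change (lurbinectedin against DMSO) of genes binned by genomic span in kb, by line, with 95% bootstrap intervals of the median from 1000 samples of genes. From 300 to 1000 kb the medians are -0.39 in H187, -0.44 in H209, -0.16 in H82 and -0.18 in SHP-77.

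**Figure D4:**
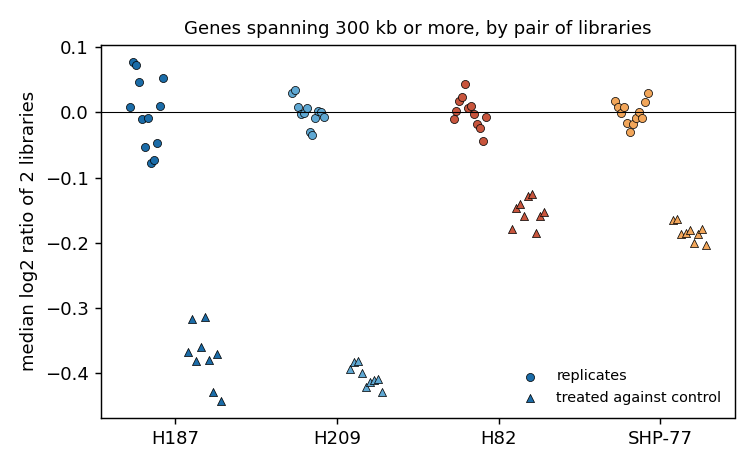
Median log2 ratio over genes spanning 300 kb or more for pairs of libraries within a line, replicate pairs (each drawn in both directions) beside the 9 treated-control pairs. Replicate pairs lie within 0.0781 of 0 and treated-control pairs from -0.442 to -0.125.

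Whether the response differs between ISL1-high and ISL1-low lines was tested as a difference of differences. ATF3 rose by 1.42 in H187 and 2.53 in H209 and changed by 0.02 in H82 and 0.01 in SHP-77, a difference of 1.96 ± 0.07 (SE, 24 libraries, adjusted p = 2.7e-22). INHBE (1.66), CHAC1 (1.62), TRIB3 (1.38), the angiogenic factor VEGFA (1.36) and SESN2 (1.32) differed in the same direction. MACROD2 fell more in the high lines (-2.61 and -2.20 against -0.76 and -0.95, difference -1.55 ± 0.16), and so did LSAMP (-1.33), GPC6 (-1.28), THSD7B (-1.27) and AKAP6 (-1.07). ROR2 differed by -1.29 ± 0.30. In the panel DLL3 (-0.35 ± 0.06), which fell in the high lines and rose in H82, and MYCL (-0.21 ± 0.04) differed. Of 11408 genes, 1812 had a higher and 1768 a lower response in the high lines, 31.4% of the total, and 31 differed at least 2-fold.

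By list, the replication genes (40 of 42 higher, 1 lower, 41 and 1 adjusted over the list alone, median 0.32, adjusted p = 2.7e-30) and the integrated stress response (24 of 25 higher, 25 adjusted over the list alone, median 0.65, 2.7e-30) responded more in the high lines. Mitosis genes (35 of 40 lower, 36 adjusted over the list alone, median -0.36, 1.0e-26) and synaptic and axonal long genes (13 of 16 lower, 13 adjusted over the list alone, -0.61, 6.1e-10) fell more there. These 4 lists kept their call with an estimated correlation (0.00011, 1.9e-07, 0.0055 and 0.0012). So did homologous recombination (19 of 28 higher, 1 lower, 0.0055), immediate early and short-lived transcripts (16 of 24 higher, 2 lower, 0.00030), NF-kB targets (9 of 14 higher, 0.0021) and heat shock genes (14 of 19 lower, 0.015). Histones (28 of 36 higher, median 0.23, 3.9e-10, and adjusted p = 0.20 with an estimated correlation) and ribosomal proteins (45 of 73 lower, -0.13, 7.2e-10, and adjusted p = 0.25 with an estimated correlation) did not keep it. Nor did oxidative phosphorylation (31 of 49 lower, 0.17 with an estimated correlation), cholesterol biosynthesis (13 of 24 lower, 1 higher, 0.15), the Fanconi anaemia pathway (7 of 21 higher, 1 lower, 0.070) and the DNA damage checkpoint (9 of 20 higher, 2 lower, 0.072). Drug response and efflux genes (4 of 9 lower, 1 higher, 0.12 with an estimated correlation) and the unfolded protein response (9 of 22 lower, 4 higher, 0.37) complete the 16 that passed.

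The spread behind these tests is that between replicate cultures of 4 fixed lines. With 1 treatment effect per line, 2 lines against 2, limma called 0 genes, with 2062 at an unadjusted p under 0.05 and a smallest adjusted p of 0.114, while DESeq2 on the libraries called 3553. Single pairs of lines gave 1154 genes for H187 against H82 and 1233 for H187 against SHP-77, and 3186 and 3413 for H209 against the same lines.

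**Figure D5:**
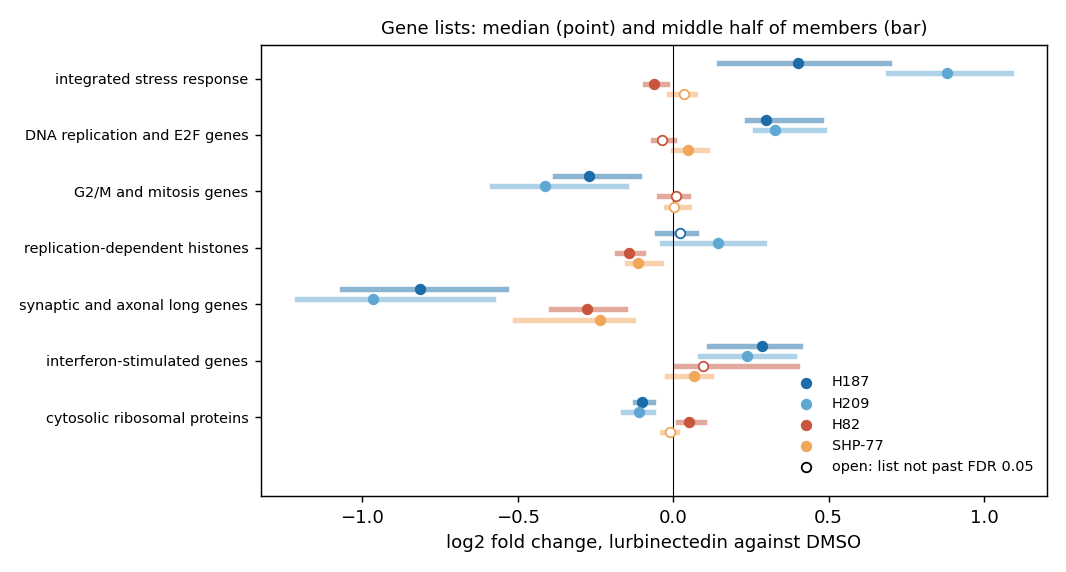
Median log2 fold change of the members of 7 gene lists in each line, with bars from the lower to the upper quartile of members, filled points where the list passed camera at an adjusted p under 0.05 and open points where it did not. The replication list lies at 0.30 in H187 and 0.33 in H209, the mitosis list at -0.27 and -0.41.

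The baseline difference between the classes was tested under DMSO. ISL1, by which the classes are named, was higher in the high lines by 6.90 ± 0.05 on the log2 scale (SE, 12 libraries, adjusted p = 4.7e-37). ILDR2 (7.04), TFCP2L1 (6.33) and ID4 (6.03) were higher there, ID4 at 295 and 719 CPM in H187 and H209 against 15.9 and 3.13 in H82 and SHP-77. The cell-cycle kinase gene CDK6 was lower (-7.07), at 1.62 and 2.24 CPM against 385 and 172. GPRIN3 (-7.04) and SLC7A2 (-5.98) were lower too. INSM1 (2.73) was called higher, but SHP-77 had as much of it as the high lines (812 CPM against 585 in H187 and 807 in H209), so H82 alone, at 13.2 CPM, carried the difference. MYCL (2.64) was at 728 CPM in H209 and 50.8 in H187, against 55.9 in H82 and 17.1 in SHP-77. Of 11408 genes, 5163 were higher and 4996 lower, 89.1% of the total. With the same sign in all 4 pairs of lines there were 4449, with class as the only term 4599. limma on 1 value per line called 0, with 819 at an unadjusted p under 0.05, and DESeq2 called 10060.

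Under DMSO the high lines had lower ribosome biogenesis genes (35 of 37 lower, 2 higher, 35 and 2 adjusted over the list alone, median -0.91, adjusted p = 8.2e-08, and 0.0071 with an estimated correlation). Cytosolic ribosomal proteins (69 of 73 lower, 3 higher, -0.85, 1.1e-10, and adjusted p = 0.55 with an estimated correlation) and heat shock genes (17 of 19 lower, -0.84, 7.5e-05, and 0.080 with an estimated correlation) were lower. So was oxidative phosphorylation (34 of 49 lower, 13 higher, 0.021, and 0.71 with an estimated correlation). Lineage transcription factors (8 of 9 higher, median 1.96, 0.0018, and 0.44 with an estimated correlation), the Fanconi anaemia pathway (16 of 21 higher, 2 lower, 0.0092, and 0.44) and histones (27 of 36 higher, 8 lower, 0.037, and 0.76) were higher. The lineage list holds ISL1 itself and lacks the members that are not among the shared genes. Those include NEUROD1 and MYC, at 268 and 1994 CPM in H82 under DMSO, and MYCN, at 80.8 CPM in H187. Under lurbinectedin, where the class comparison covers these 3 genes, the lineage list was not among the 9 that passed. Each class holds 2 lines, so a difference of class and a difference of particular lines were not separable here.

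Under lurbinectedin the class comparison also covered genes absent from some line tables. SLFN11 (hg38 chromosome 17, 35350310 to 35373701) stood at 94.7 ± 2.39 CPM in H187 and 164 ± 2.05 in H209 and had 0 counts in the 6 treated libraries of H82 and SHP-77. That is at least 841-fold higher in the lower of the high lines, against a floor of 3 counts per library. On the same floor MT1E, a metallothionein, was at least 150.0-fold and UBASH3B at least 64.1-fold higher. MAGEB2, GTSF1 and GRIK1 were at least 15.4-fold, 9.9-fold and 11.6-fold higher in the lower of the low lines. SOX1 (199 and 326 CPM) and CDH1 (108 and 332 CPM) had 0 or 1 counts in each treated low library. MYC stood at 2106 CPM in H82 and 80.3 in SHP-77, against 0.354 in H187 and 0.123 in H209. ISL1 differed by 6.80 ± 0.05. NEUROD1 was not called (-0.07 ± 0.41), as H82 had 306 CPM and SHP-77 0.0347, and the log2 fold change in the authors' deposited table was -4.68. Of 14463 genes, 6798 were higher and 6060 lower, 88.9% of the total. The same sign in all 4 pairs of lines held for 5778, class as the only term gave 5644, and 5478 passed in the authors' deposited table. limma on 1 value per line called 0, with 1108 at an unadjusted p under 0.05, and DESeq2 called 12765.

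Epithelial markers were higher in the treated high lines (16 of 17 higher, 1 lower, adjusted p = 2.0e-05, and 0.028 with an estimated correlation), with ESRP1 at 229 and 405 CPM against 0.371 and 0.0473. KRT8 was carried by H82 (0.127 CPM), since SHP-77 had 320 CPM. Epithelial markers were not tested under DMSO, as fewer than 5 of them are among the 11408 shared genes. Within lines they did not pass in H187, H209 or SHP-77 (camera adjusted p = 0.88, 0.92 and 0.23). Interferon-stimulated genes had 9 members among the shared genes, against 27 here. A list that passed here and not under DMSO is therefore no sign of an effect of treatment. Ribosomal proteins (69 of 73 lower, 3 higher, median -1.01, 2.1e-13, and 0.45 with an estimated correlation), ribosome biogenesis (35 of 37 lower, 2 higher, -0.97, 1.5e-08, and 0.050) and oxidative phosphorylation (38 of 49 lower, 7 higher, 5.4e-05, and 0.47) were lower. Heat shock genes (18 of 21 lower, 2 higher, 7.2e-05, and 0.17 with an estimated correlation) and the unfolded protein response (17 of 22 lower, 3 higher, 0.0062, and 0.47) were lower too. Histones (36 of 43 higher, 4 lower, 7.2e-05, and 0.59 with an estimated correlation), the Fanconi anaemia pathway (18 of 21 higher, 2 lower, 0.0024, and 0.051) and interferon-stimulated genes (21 of 27 higher, 3 lower, 0.0024, and 0.051) were higher.

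Several lists did not pass camera in any of the 4 lines, although fry, which does not compare a list with other genes, called some of them. Nucleotide excision repair, which removes bulky adducts, gave adjusted p = 0.88, 0.60, 0.62 and 0.81 in H187, H209, H82 and SHP-77. RNA polymerase II transcription machinery gave 0.32, 0.57, 0.32 and 0.81, BCL2 family and caspases 0.12, 0.17, 0.32 and 0.81, and antigen presentation 0.19, 0.43, 0.26 and 0.81. Tumour surface targets gave 0.12, 0.60, 0.79 and 0.18, and LIM homeodomain and motor neuron genes 0.88, 0.15, 0.32 and 0.39. Cytosolic DNA sensing, with 5 or 6 members measured, gave 0.19, 0.20 and 0.81 in H187, H209 and SHP-77. Of 18 leukocyte markers 5 were in any table, too few to test within a comparison, and fibroblast and endothelial markers did not pass in H82 (0.94) or SHP-77 (0.81). fry called BCL2 family and caspases and cytosolic DNA sensing in H187 (0.0049 and 0.025) and H209 (0.0058 and 0.023), and tumour surface targets in H187 (0.0028) and SHP-77 (0.048). In H209 it also called LIM homeodomain and motor neuron genes (0.00079) and, at 0.016 each, nucleotide excision repair and the transcription machinery.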

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

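In this part, the tests of S phase in H209 and in H187, of the spread between replicates, of a smaller response like that of H187 or of H209, of a span bias between libraries and of a shift of scale were chosen after the results were seen. Each result here was singled out because the response to lurbinectedin differed between the ISL1-high and the ISL1-low lines in a test of that difference. The difference was positive for 1812 genes and negative for 1768. By list median it was 0.32 for the DNA replication and E2F genes, 0.65 for the integrated stress response, -0.36 for the G2/M and mitosis genes and -0.61 for the synaptic and axonal long genes. It was 0.23 for homologous recombination, 0.30 for immediate early and short-lived transcripts, -0.16 for heat shock genes and 0.20 for NF-kB targets. By gene it was 1.96 for ATF3, 1.66 for INHBE, 1.62 for CHAC1, 1.38 for TRIB3, 1.36 for VEGFA and 1.32 for SESN2. It was -1.55 for MACROD2, -1.33 for LSAMP, -1.29 for ROR2, -1.28 for GPC6, -1.27 for THSD7B and -1.07 for AKAP6. In ROR2 and THSD7B 1 low line had a fold change of the opposite sign (0.55 in H82 and 0.25 in SHP-77).

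Long genes fell in all 4 lines, with Spearman's rho of fold change and genomic span at -0.261, -0.256, -0.330 and -0.282 across genes, which are not independent replicates. Genes with GC-rich transcripts did not fall more in the fits, where the lowest rho with GC content was 0.157. Replicate pairs of a group reached a rho 0.331 from 0 in H187, 0.249 in H209, 0.365 in H82 and 0.455 in SHP-77. A GC bias between libraries could thus set that sign, so the test does not decide the question. The tables argue against exonic length, expression or GC content in place of the span, since the partial rho nearest to 0 was -0.178. They also argue against a span bias between libraries, since no replicate pair had a median over genes of 300 kb or more beyond 0.0781 from 0, less than any treated-control pair, although an earlier form of this test on rho had left it undecided (0.253 in an H187 replicate pair against a treated-control median of -0.236). A shift of scale by a few abundant transcripts would move long and short genes alike, and is argued against, since the median over genes of 300 kb or more minus that of genes under 10 kb was -0.21 or lower in each line (largest SE 0.03, from resampled genes). An earlier form of this test, which left those transcripts out, moved the medians by less than their standard errors and so tested little. A candidate explanation is that a block to elongation lowers the RNA of long genes more. The rho of -0.256 or lower in each line goes with that but does not show a fall in proportion to length. For genes of 30 to 100 kb the medians were 0.010 in H187, 0.0096 in H209, -0.0087 in H82 and -0.00070 in SHP-77. This explanation was not tested against transcription itself.

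Replication genes rose and mitosis genes fell in H187 and H209. With an estimated correlation only replication in H187 kept its call (adjusted p = 0.027), against 0.058 for replication in H209 and 0.25 and 0.058 for mitosis in H187 and H209. A trend with span, exonic length and expression is argued against, since the median residual nearest to 0 over both lists and both lines was 0.296 in the list's own direction. A larger share of cells in S phase may explain H209, where 29 of 41 histone genes were higher and 7 lower (exact binomial p = 3.1e-04, two-sided), although that list lost its call with an estimated correlation (adjusted p = 0.62). In H187 that stays open, with 5 of 44 higher and 4 lower (exact binomial p = 1). In H82 and SHP-77 0 histone genes were higher and 13 and 18 lower (exact binomial p = 2.4e-04 and 7.6e-06, edgeR calls). Near-identical histone copies share reads, so these calls are not independent. The exact tests also assume an even split, which short genes did not show. Of all genes under 10 kb, 893 were higher and 529 lower in H209, 80 and 21 in H82 and 80 and 49 in SHP-77. The p for H209 therefore overstates how far its histone genes depart from other short genes.

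Fewer genes changed in the ISL1-low lines. The biological coefficient of variation was 0.0332 in SHP-77 and 0.0408 in H82, above H209 (0.0308) and below H187 (0.0428), and H82 had 1397 genes without DMSO 3, so the spread may bear on its count. A larger spread as the whole cause is argued against in both lines, since noise does not shrink a median and the genes called in a high line moved less there. In the direction of the call their median log2 ratio was at most 0.0495 in the 9 treated-control pairs of H82 and 0.0552 in those of SHP-77. For genes called in H187 it was at least 0.209 in H209 pairs, and for genes called in H209 at least 0.102 in H187 pairs. A response scaled down by 1 factor would move the stress response, replication and mitosis lists by the factor of the synaptic and axonal long genes, which was 0.368 from H187 to H82, 0.306 from H187 to SHP-77, and 0.295 and 0.263 from H209. In H82 all 3 lists lay off the scaled value, from H187 and from H209, by more than 2 SE and outside the 9 treated-control pairs. That SE comes from resampled list members, which are not independent replicates, and holds no spread between cultures. The 9 pairs share libraries. The stress response, for example, stood at -0.06 against a scaled 0.15 from H187. A smaller response of the same kind is argued against there, and also in SHP-77 against H209, where 2 of the 3 lists lay off. In SHP-77 against H187 it stays open, since 1 of the 3, mitosis, lay off. A lower effective dose, at which some lists do not respond yet, was not tested. An earlier form of this test took the share in opposite directions, 113 of 557 genes called in H209 and in a low line (20.3%) and 29 of 406 for H187 (7.14%), which does not see lists that stay still in the low lines. ISL1 itself, and any other property of these lines, could not be separated with 2 lines per class.

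The splits are too few to give a share under 0.05. Within a line, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes: 3486 in H187, 6513 in H209, 395 in H82 and 737 in SHP-77, with highest other counts of 0, 0, 4 and 0. Of the 3 ways to part the 4 lines into pairs, 1, the real one, gave the most genes: 3580 for the difference in response with a highest other of 718, 10159 for the classes under DMSO with 10076, and 12858 under lurbinectedin with 12731. That other pairings of the lines call nearly as many genes in the class comparisons points to differences between the single lines.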

How the results depend on the processing

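In this part the GC correction, the single pairs of lines and, for the genes shared by the 4 lines, the libraries left out, the other filters and DESeq2 were chosen after seeing the data. Of 4142 alternative values of 227 named gene results, 3916 kept their side of the threshold, 202 no longer passed and 24 newly passed. Among values that passed in the main or the alternative fit, 0 turned direction. Direction was not compared where a gene passed in neither fit. In all, 123 gene results changed in at least 1 alternative. RLE size factors, a mean of at least 1 CPM and DESeq2 kept every total of genes within 1.5 times its value, though not every count by direction: with DESeq2 the genes higher in H82 fell to 130 and those higher in all 4 lines from 6 to 3. Leaving out the filter tested nothing, since the default filter removed none of the listed genes, and 227 of the 3916 values that kept their call are from that setting. Requiring at least a 2-fold change left 114 genes in H187, 231 in H209, 8 in H82, 13 in SHP-77, 31 for the difference in response, and 2804 and 5199 for the classes under DMSO and lurbinectedin, by construction. In H82 the 395 genes became 755 (446 higher, 309 lower) with a replicate block, 643 (270, 373) with all 24 samples in 1 fit, 652 (374, 278) in the authors' deposited table and 180 (40, 140) with the GC correction, of which 146 were among the 395. In SHP-77 the 737 became 451 with all 24 samples in 1 fit. For the difference in response, limma on 1 value per line called 0 (2062 at an unadjusted p under 0.05, edgeR 3580, DESeq2 3553), and 1154 and 1233 genes differed between H187 and H82 or SHP-77 alone, with fewer samples. For the classes, limma on 1 value per line called 0 under DMSO and 0 under lurbinectedin (819 and 1108 unadjusted, edgeR 10159 and 12858, DESeq2 10060 and 12765). Class as the only term gave 4599 and 5644, the same sign in all 4 pairs of lines 4449 and 5778, and 5478 passed in the authors' deposited table under lurbinectedin. The 69 genes shared by the 4 lines became 277 (70 higher, 207 lower) when 3 lines and the sign in the other were enough, 104 (10, 94) with all 24 samples in 1 fit and 54 (0, 54) with the GC correction. The cause of these differences was not tested, except where the construction gives it.

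Leaving out 1 library at a time gave 2402 to 3211 genes in H187, 5733 to 6033 in H209, 93 to 1397 in H82 and 417 to 706 in SHP-77. It gave 3333 to 3689 for the difference in response, 10041 to 10131 and 12744 to 12789 for the classes, and 30 to 102 for the genes shared by the 4 lines. The highest counts in H82 (1397) and for the shared genes (102) were those without H82 DMSO 3.

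Lists that passed fell from 17 to 6 in H187, 16 to 2 in H209, 9 to 0 in H82, 7 to 0 in SHP-77, 16 to 8 for the difference in response, 7 to 1 under DMSO and 9 to 1 under lurbinectedin when camera estimated the correlation. In H82 and SHP-77, where that left 0, fry called 2 and 7. With the GC correction 8 lists passed in H82 and 8 in SHP-77. fry called 26 in H209, and 27 and 32 for the classes. With 3 libraries per group the estimated correlation is itself uncertain. Replicate numbers showed no sign of pairing the samples across all groups. Over 84 pairs of libraries with the same number the mean correlation of residuals was -0.0041. The mean for different numbers, 0.0020, follows from centring each group and is no separate reference. Within lines the correlation for the same number ran from -0.211 in SHP-77 to 0.182 in H82. The replicate block is therefore given only as an alternative.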

Other observations

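The genes in this paragraph were chosen after their values were seen. Some BH3-only genes, whose products start apoptosis, rose in the ISL1-high lines: BBC3 by 0.90 in H187 and 2.35 in H209, HRK by 0.63 and 1.81, and PMAIP1 by 0.26 and 1.15. The difference in response was 1.27 for BBC3 (adjusted p = 1.7e-08) and 0.84 for PMAIP1 (adjusted p = 8.2e-14), and in H82 BBC3 changed by 0.48 without passing (adjusted p = 0.054). BCL2L11 rose little (0.12 and 0.09), BMF rose in H209 (0.28) and did not pass in H187 (-0.03), and BIK fell in H187 (-0.25) and did not pass in H209 (0.15). ULBP1, a ligand of the NK-cell receptor NKG2D, rose by 1.34 in H187 and 1.21 in H209 and did not pass in H82 (-0.23). The 45S ribosomal RNA precursor ranged from 7.32 to 764 CPM between libraries, and from 11.8 to 314 CPM among the 3 treated H187 libraries.

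In H82 genes with GC-rich transcripts had higher fold changes (Spearman's rho 0.447 across genes, which are not independent replicates, against 0.208, 0.157 and 0.210 in H187, H209 and SHP-77). A GC bias between libraries was not particular to H82. Replicate pairs reached a rho 0.331 from 0 in H187, 0.249 in H209 and 0.455 in SHP-77. The medians of the treated-control pairs in these lines were smaller, at 0.183, 0.138 and 0.140. The largest rho between H82 replicates of the same group was 0.365, between DMSO 2 and DMSO 3, and DMSO 1 and DMSO 3 gave 0.335, within the range of the 9 treated-control pairs (0.0577 to 0.516, median 0.408). An effect of treatment and a GC bias between libraries cannot be told apart here, since DMSO 3 differs from the other DMSO libraries almost as much as the groups do. This test was chosen after the trend was seen and before its own value was computed.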
